A study of Homo sapiens with 2 samples.

How the data were processed

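Total RNA was measured on 2 single-channel oligonucleotide expression arrays. The RNA came from HCT116 cells, an established human colorectal carcinoma line. One sample had received a control siRNA and the other siRNAs against JMJD1A (KDM3A) and JMJD1B (KDM3B), 2 days earlier, per the labels. The siRNA sequences were not given in the sources used here, so off-target matches were not tested, and a difference need not reflect loss of the targets. Biotin-labelled material was prepared from 0.5 ug of total RNA by the array maker's routine procedure, per the labels' protocols. Each group held 1 array, so no replicate error, no test and no p-value could be given for any difference, and the number of arrays limits the precision of every value. A difference between the arrays is a difference between these samples and hybridizations, not an estimate for the conditions.

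The authors deposited 1 table with a linear signal intensity for each of 54675 probe sets on each array. The values were made with MAS5, per the submitters' processing notes, with its version and settings not given in the sources used here. As a general description, MAS5 subtracts a local background, combines the perfect-match and mismatch probes of a probe set and multiplies each array by 1 factor. In the deposited intensity values the mean after trimming 2% of probe sets at each end was 500.1 on both arrays, so each array had been scaled as a whole. Detection calls and scale factors were not used here. Both deposited columns were matched to a sample and none was left unmapped.

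Probe sets were named from the platform annotation. Of the non-control probe sets, 41091 carried 1 gene symbol, 1801 carried several and 11721 carried none. Of those with 1 symbol, 41037 had a gene identifier found in the current RefSeq gene table, and no symbol changed on updating. Probe sets with several symbols or none were not assigned to a gene. Of the 420 distinct genes in the 27 fixed lists, 39 had no probe set with a single symbol and were not analysed here, and 328 were measured.

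Signals were taken to log2 with no pseudocount and the deposited scaling was kept. Each gene was represented by its probe set with the highest mean log2 signal over both arrays. A gene counted as measured if that mean reached the median of all non-control probe sets, a signal of 50.4. This left 12561 genes. The log2 ratio is the JMJD1A/JMJD1B siRNA array minus the control array. Genes changed at least 2-fold were counted, with about 8.91% of all measured genes at least 2-fold higher and 8.53% at least 2-fold lower as the background for each list. For each list the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. Where the dimmer of a gene's signals lay under 50.4, a second fold was computed with that signal raised to 50.4. It is given with the words "at least" as a lower bound against the filter, and it allows for no error in the brighter signal.

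The spread between probe sets of one gene was used as the only measure of technical scatter. Over the 6192 genes with 2 or more measured probe sets, the SD of a single probe set's log2 ratio was 0.53, from the differences between the 2 brightest. This covers probe behaviour within these arrays and not the spread between samples. All calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, and statsmodels 0.14.6 for loess. The procedure was tested on simulated data with 200 genes changed 4-fold among 12558 and a noise SD of 0.2 per array. It recovered 100% of the changed genes at 2-fold in the right direction and called 6 unchanged genes. The simulated noise was lower than the scatter between probe sets in these data. These figures therefore give no rate of false calls for the 2-fold counts here. Of 100 unshifted lists, 4 fell outside the central 95% of random medians. These lists were drawn at random from simulated genes with independent noise. The figure therefore checks the calculation only and gives no rate for lists whose genes vary together.

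The genes named were fixed by a rule before the data were examined, as were the lists, the filter and the alternatives, except where stated. The rule takes KDM3A, KDM3B and JMJD1C, and the 12 genes with the largest rise and the 12 with the largest fall whose measured probe sets all went in that direction. It takes up to 4 members of each list with the largest change among those changed at least 2-fold, or the 1 with the largest change where none was. It also takes AXIN2, LGR5, ASCL2, MYC and CCND1. The alternatives were 3 other scalings, a pseudocount, 3 other filters, 2 other rules for probe sets, and fold thresholds of 1.5 and 3. A scaling on the hybridization controls and a filter that left out the brightest 10% of genes were added after seeing the data.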

Results

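Gene expression was profiled in HCT116 human colorectal carcinoma cells 2 days after transfection with a control siRNA or with siRNAs against JMJD1A and JMJD1B. These are the older names of KDM3A and KDM3B, demethylases that act on lysine 9 of histone H3. The comparison asks which transcripts differ between cells given these siRNAs and cells given the control siRNA, and the arrays are named here by their labels. Each condition was represented by 1 array, so the values below carry no replicate error and no test. The median signal over the 54675 probe sets was 52.2 on the control array and 55.4 on the JMJD1A/JMJD1B siRNA array. The 3′ to 5′ signal ratio of the GAPDH control probe sets was 0.914 on the control array and 0.923 on the JMJD1A/JMJD1B siRNA array, and that of the ACTB control probe sets was 1.59 and 1.77.

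KDM3B transcript was much lower on the JMJD1A/JMJD1B siRNA array, while KDM3A transcript was nearly level on the deposited scale. The brighter KDM3B probe set read 3031 in control cells and 496 in cells given the JMJD1A/JMJD1B siRNAs, a 6.11-fold difference and a log2 ratio of -2.61. The second KDM3B probe set read 2765 and 315, a log2 ratio of -3.13. The KDM3A probe set read 3884 and 3323, so that 85.6% of the control signal was left, with a log2 ratio of -0.22. That difference is smaller than the SD of 0.53 that probe sets of one gene showed among themselves, but with the arrays set level on their hybridization controls KDM3A would stand at -0.84, beyond that SD. A second KDM3A probe set lay below the signal filter, at 16.9 and 9.18. The third family member, JMJD1C, was not targeted, and its 3 measured probe sets had log2 ratios between 0.34 and 0.60, which would lie below 0 with the arrays level on those controls.

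**Figure D1:**
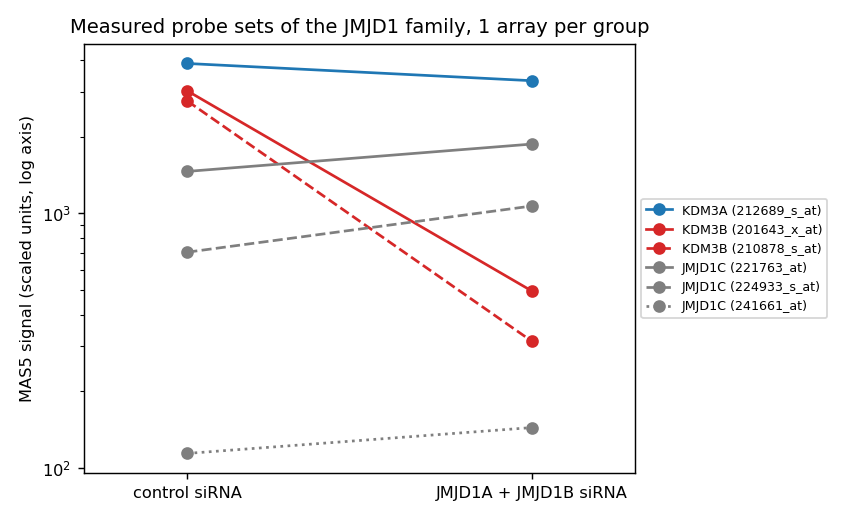
MAS5 signal (log axis, scaled units) of each measured probe set of KDM3A, KDM3B and JMJD1C on the control array and on the array of cells given JMJD1A and JMJD1B siRNA, with 1 line per probe set and 1 array per group. Both KDM3B lines drop, to 496 and 315, while the KDM3A line stays between 3884 and 3323.

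Across 12561 measured genes, 1119 were at least 2-fold higher and 1072 at least 2-fold lower on the JMJD1A/JMJD1B siRNA array. A 4-fold difference was reached by 122 genes in the higher and 112 in the lower direction. Among the 12 genes with the largest rise, those above the signal filter on both arrays were led by CXCR4, the chemokine receptor for CXCL12, which read 97.4 and 1681 (17.3-fold, with its 3 measured probe sets between 2.28 and 4.11 on the log2 scale), and FOS, a subunit of the AP-1 transcription factor, which read 164 and 2766 (16.9-fold). LEMD1 was 16.6-fold higher, ANKRD37 12.03-fold, the secreted lipoprotein lipase inhibitor ANGPTL4 11.2-fold, and AGPAT4 10.5-fold (probe sets at 2.44 and 3.39). For the others the control signal lay under the filter, so lower bounds against the filter are given, with no allowance for error in the brighter signal. OLFML2A was at least 8.05-fold higher, SNAI2, a repressor of epithelial genes, at least 8.21-fold, WFDC3 at least 7.75-fold, and the non-coding transcripts COPB2-DT, UNC5B-AS1 and IRAG1-AS1 at least 6.26-fold, 5.49-fold and 3.87-fold.

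Among the 12 genes with the largest fall, those above the filter on both arrays were led by SEC23IP, a protein of the secretory pathway, which read 3285 and 211 (15.6-fold lower, with its 3 measured probe sets between -4.76 and -3.58). SLC68A1 was 11.2-fold lower. WARS1, the cytosolic tryptophanyl-tRNA synthetase, was 10.7-fold lower (probe sets at -3.41 and -2.22). LINC01806 was 8.91-fold lower (probe sets at -3.16 and -1.17) and ERVMER34-1, an endogenous retroviral envelope gene, 7.54-fold lower. For the remaining genes the signal on the JMJD1A/JMJD1B siRNA array lay under the filter. LONRF2 was at least 7.82-fold lower, the anion exchanger gene SLC4A2 at least 8.16-fold, PHKG2, a catalytic subunit of phosphorylase kinase, at least 5.90-fold, TRPV2 at least 4.16-fold, ANHX at least 3.69-fold, BCL9, a coactivator of beta-catenin, at least 3.36-fold, and SH2D2A at least 3.11-fold.

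Probe sets of one gene agreed in direction more often than in size. Among 506 genes at least 2-fold higher by their brightest probe set and with a second measured one, the second was also higher in 439 (86.8%) and at least 2-fold higher in 226 (44.7%). Among 540 such genes at least 2-fold lower, the second was lower in 457 (84.6%) and at least 2-fold lower in 233 (43.1%). Across these 6192 genes the log2 ratios of both probe sets correlated with a Pearson r of 0.56, over genes, which are not independent replicates. Of 33 named genes changed at least 2-fold and with 2 or more measured probe sets, 8 were under 2-fold by the mean of these, namely AXIN2, SOX9, EP300, TLE3, MCL1, LSS, KDM4B and AJUBA. The deposited scaling set both arrays to one trimmed mean. The 18 hybridization control probe sets, which report bacterial and phage transcripts added in equal amounts before hybridization in the array maker's procedure, were nevertheless all higher on the JMJD1A/JMJD1B siRNA array, by a median of 0.61 on the log2 scale. Setting the arrays level on these controls instead would lower every log2 ratio by that amount and leave 270 genes at least 2-fold higher and 3483 at least 2-fold lower, so that 7.19% in place of 51.1% of the changed genes would be higher. All ratios here are on the deposited scale, and any log2 ratio or list median between 0 and 0.61 would turn negative on the scale of the controls. The 18 control probe sets report only the bioB, bioC, bioD and cre transcripts, so their shared rise is not 18 independent observations.

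**Figure D2:**
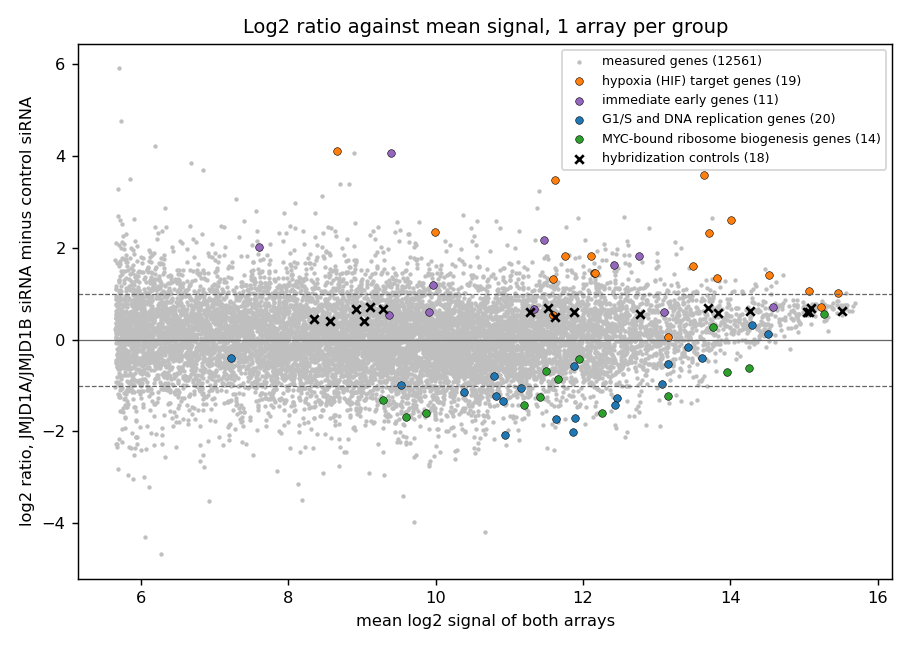
Log2 ratio of the JMJD1A/JMJD1B siRNA over the control array (vertical axis) against the mean log2 signal of both arrays (horizontal axis) for 12561 measured genes, with 4 gene lists and the 18 hybridization controls marked and dashed lines at 2-fold. Above the upper dashed line lie 16 of 19 HIF target and 6 of 11 immediate early genes, below the lower one 10 of 20 replication and 7 of 14 ribosome biogenesis genes, and the controls lie between 0.40 and 0.71.

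The Wnt/beta-catenin target genes, a programme that is constitutively active in this line, went both ways. Of 17 measured members, 5 were at least 2-fold higher, 1 was at least 2-fold lower and 11 changed less. AXIN2, a feedback inhibitor of the pathway, was 2.01-fold lower, with probe sets at -1.01 and -0.80. MYC had a log2 ratio of -0.43 and CCND1, encoding cyclin D1, one of -0.44, both under the probe-set SD of 0.53, although a dimmer CCND1 probe set read -1.36. On the scale of the hybridization controls MYC would stand at -1.04 and CCND1 at -1.06, both beyond that SD. PLAUR, the urokinase receptor, was 4.26-fold higher, TNFRSF19 at least 2.40-fold higher, SOX9 2.27-fold higher (probe sets at 1.18 and 0.77) and NOTUM 2.21-fold higher. By the mean of each gene's probe sets, 3 of the 17 were at least 2-fold higher and none at least 2-fold lower. The stem cell genes LGR5 and ASCL2 had no probe set above the filter on these arrays. The list median was 0.07, at the 37.3rd percentile of random lists of matched signal, and -0.54 on the scale of the hybridization controls, with the same percentile by construction. On that scale 2 of the 17 would be at least 2-fold higher and 3 at least 2-fold lower. Among 21 measured components of the pathway, 4 were at least 2-fold lower and 1 was at least 2-fold higher. Besides BCL9, the acetyltransferase EP300 was 2.61-fold lower by its brightest probe set, with the other at -0.47, and the corepressor TLE3 2.60-fold lower, with its 4 probe sets between -1.38 and -0.10, while TCF7L1 was 2.73-fold higher. By the mean of probe sets 2 members were at least 2-fold lower, BCL9 and CREBBP. CREBBP, named outside the rule, was 2.14-fold lower by its brightest probe set, with probe sets at -1.10 and -1.05. EP300 stood at -0.93 and TLE3 at -0.77 by that mean. The median of this list was -0.15, at the 12.8th percentile.

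Target genes of the hypoxia-inducible factors (HIF) stood highest of all lists with 3 or more measured members. All 19 measured members had a ratio above 0 and 16 were at least 2-fold higher, with a list median of 1.46 (2.75-fold), above all 10000 random medians, whose central 95% ended at 0.56. A dimmer SLC2A1 probe set read -0.10. By the mean of each gene's probe sets 12 of the 19 were at least 2-fold higher, and after loess or quantile normalization 13. CXCR4, ANKRD37 and ANGPTL4 are described above, and NDRG1 was 6.07-fold higher (6713 and 40747). On the scale of the hybridization controls the median was 0.85 and 8 of the 19 genes were at least 2-fold higher, and leaving out _x_at and _s_at probe sets left 8 of 12. Immediate early genes, which respond within minutes to growth factors and stress, were also higher. All 11 measured members had a ratio above 0 and 6 were at least 2-fold higher, with a median of 1.20 that lay above all random medians. Besides FOS, DUSP1 was 4.48-fold higher, FOSB 4.05-fold and EGR1 3.52-fold. On the scale of the hybridization controls the median of this list was 0.59.

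Genes of DNA replication were lower. Of 20 measured members of the G1/S and replication list, 10 were at least 2-fold lower and none at least 2-fold higher, with a median of -1.02, below all 10000 random medians. The replicative helicase subunits led the list. MCM5 was 4.19-fold lower, MCM2 4.05-fold, MCM4 3.29-fold and MCM3 3.25-fold. Genes in the list of MYC-bound ribosome biogenesis genes were also lower, with 7 of 14 at least 2-fold lower, none at least 2-fold higher and a median of -1.04, below all random medians. MYC binding was not measured here. CAD, the enzyme that starts pyrimidine synthesis, was 3.23-fold lower, NOP58 3.02-fold, RRP9 3.01-fold and the spermidine synthase SRM 2.69-fold. CAD and SRM serve nucleotide and polyamine synthesis and not the ribosome itself. Mitosis genes differed less, with 2 of 18 at least 2-fold lower (KIF11, a spindle motor, 2.93-fold, and the kinase PLK1 2.02-fold) and a median of -0.39 at the 0.65th percentile. Without _x_at and _s_at probe sets that median turned to 0.09.

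Of the 27 lists, 9 had a median outside the central 95% of random medians, against 1.35 expected for unrelated lists of independently drawn genes. Genes of one list may vary together and some lists share genes, so these 2 numbers are no test. Besides the 5 above, interferon-stimulated genes had a median of 0.53 (98.6th percentile) with 2 of 14 members at least 2-fold higher (OASL 2.43-fold, IFIT1 2.14-fold) and 2 at least 2-fold lower (OAS3 2.66-fold, IFI44 3.20-fold by its signals and at least 1.95-fold against the filter), and on the scale of the hybridization controls the median turned to -0.08. Mesenchymal genes had a median of 0.67 (98.2nd percentile), with SNAI2 and ZEB1 (3.13-fold, its other probe set at 0.88 on the log2 scale) at least 2-fold higher among 8. TGF-beta target genes had a median of 0.62 (97.52nd percentile), with 4 of 10 at least 2-fold higher, namely SMAD7 (4.09-fold), CDKN2B (3.22-fold), BHLHE40 (3.14-fold) and PMEPA1 (at least 2.74-fold). On the scale of the hybridization controls the mesenchymal median would be 0.06 and the TGF-beta median 0.01. Of the 9 alternatives that could move a percentile, mesenchymal and TGF-beta target genes stayed outside the random range under 4 each, and interferon-stimulated and mitosis genes under 7 each. Ribosomal protein genes, which were bright on both arrays, had a median of 0.73 (99.6th percentile) with none of 17 changed 2-fold, RPS19 having the largest ratio at 0.79, and the median was 0.17 (88.5th percentile) after removal of the trend with signal by loess.

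The remaining lists lay within the random range on the deposited scale. Among 20 p53 targets, 5 were at least 2-fold higher and 1 was at least 2-fold lower, with CDKN1A, the cyclin-dependent kinase inhibitor p21, 3.02-fold higher, PLK2 2.501-fold higher, GDF15 2.21-fold higher and TIGAR 2.37-fold lower, and a list median of 0.08. On the scale of the hybridization controls 0 of the 20 would be at least 2-fold higher and 6 at least 2-fold lower, with a median of -0.53. Of 12 epithelial genes 3 were at least 2-fold higher, CLDN4 (2.58-fold), KRT19 (2.39-fold) and CDH1 (2.16-fold), with a median of 0.58 at the 96.6th percentile. After loess that median was 0.43 and after quantile normalization 0.45, both above the random range (98.43rd and 98.63rd percentile). In the stem cell list, 2 of 9 were at least 2-fold higher, SOX9 and ALCAM (2.48-fold). In the intestinal differentiation list it was 1 of 6, CEACAM5 (2.43-fold by its signals, at least 1.88-fold against the filter). In the apoptosis list BIRC2 (2.14-fold) and MCL1 (2.11-fold, with its 6 probe sets between 0.25 and 1.49) were at least 2-fold higher among 15. Among 11 inflammatory genes only CXCL8 (3.30-fold higher) changed 2-fold. Of 16 stress response genes, 3 were at least 2-fold higher and 2 at least 2-fold lower, with DNAJB9 2.87-fold, DDIT3 2.35-fold and ATF3 2.29-fold higher and CHAC1 2.60-fold lower. The lists of cholesterol synthesis and YAP/TEAD targets also went both ways. In the former MSMO1 was 2.14-fold higher, and LSS was 2.23-fold lower by its brightest probe set, with another at 1.26. In the latter LATS2 was 2.73-fold higher, CCN2 at least 2.06-fold higher, F3 2.01-fold higher and AJUBA 2.01-fold lower.

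Among other enzymes and readers of H3K9 methylation, 14 of 16 changed less than 2-fold. EHMT2, an H3K9 methyltransferase, was 2.55-fold lower and the demethylase KDM4B, also in the HIF list, was 2.498-fold higher with its 5 probe sets between 0.04 and 1.32. The list median was -0.26, inside the random range, and it was -0.40 after loess and -0.37 after quantile normalization, both below the random range (1.67th and 2.01st percentile). In the H3K4 methyltransferase list WDR5 was 2.66-fold lower, MEN1 2.27-fold and KMT2D 2.03-fold lower, with none of 11 members 2-fold higher and a median of -0.35 at the 10.99th percentile. Respiratory chain genes had a median of 0.53 at the 90.1st percentile, with NDUFB5 the largest at 0.90 and none of 17 changed 2-fold. Markers of other cell types were mostly below the filter. The measured ones were 2 of 9 for fibroblasts, 2 of 10 for leukocytes and 1 of 7 for endothelium, with COL1A1 at 0.96, CSF1R at 0.57 and PECAM1 at 0.44 on the log2 scale, none of them 2-fold.

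**Figure D3:**
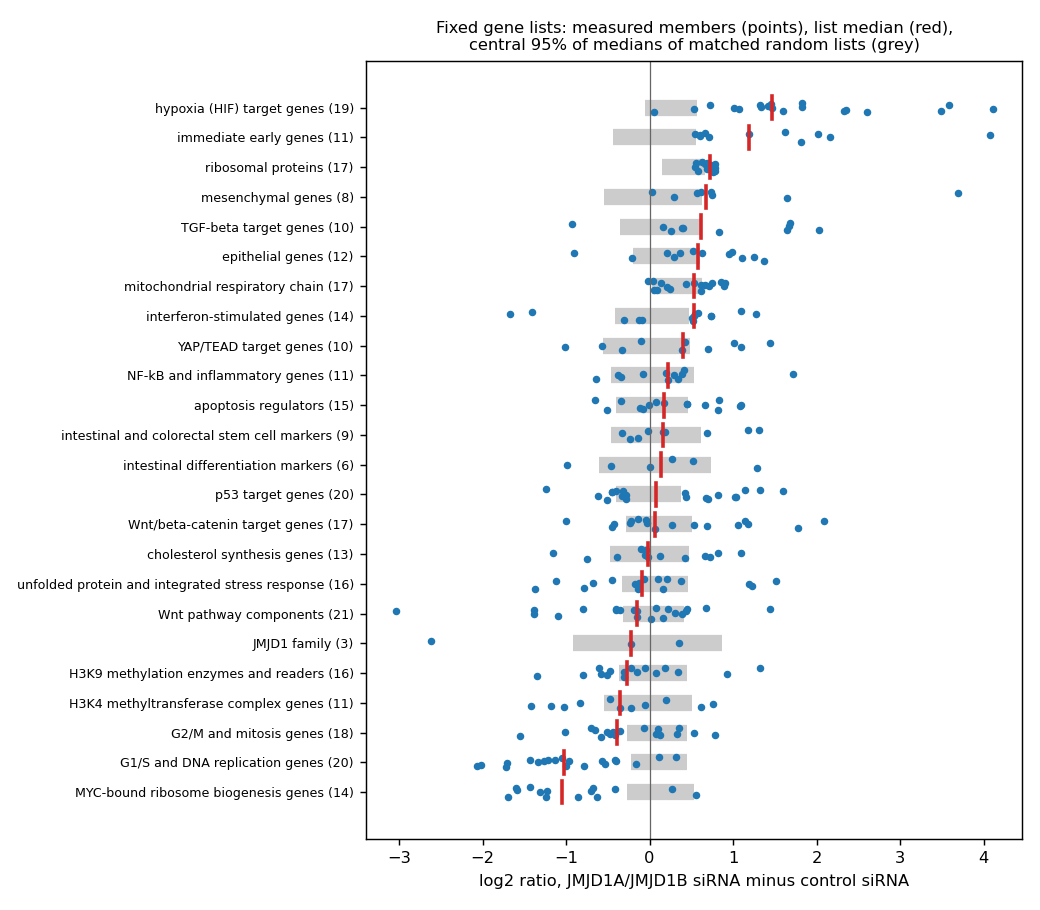
Log2 ratio of the JMJD1A/JMJD1B siRNA over the control array (horizontal axis) for the measured members (points) of each fixed list with 3 or more of them, whose number stands beside its name, with the list median (red bar) and the central 95% of medians of 10000 random lists matched on signal (grey band). The HIF target (1.46) and immediate early (1.20) medians lie right of their bands, and the replication (-1.02) and ribosome biogenesis (-1.04) medians lie left of theirs.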

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

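The tests on culture conditions, on the KDM3A probe set and on the scaling to the hybridization controls were chosen when the values that decide them were already known, and the tests on second gene lists were chosen after the first lists had been seen, with only the values of the second lists and of loess not seen beforehand. Outside the gene comparison, the 18 hybridization controls were higher on the JMJD1A/JMJD1B siRNA array by a median log2 ratio of 0.61 (range 0.40 to 0.71). Their median excess over gene probe sets of similar signal was 0.43 (range -0.05 to 0.79), while the 4 cre controls, the brightest, did not stand clear of such genes (excess -0.05 to 0.03). Of 3947 measured probe sets that carry no single gene name, 354 were at least 2-fold higher and 396 at least 2-fold lower, signals that the gene comparison leaves out. Off-target effects of the siRNAs were not tested for any pattern here.

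HIF target genes were higher on the JMJD1A/JMJD1B siRNA array. A trend of the ratio with signal is argued against by the list median of 1.38 after loess. A scale difference of the size the hybridization controls show would leave a median of 0.85. That value follows from subtracting a known shift, so it is no test, and the list's place among random lists stays the same by construction. The choice of genes is argued against by a second list of 26 other HIF targets, 22 of them measured, whose median was 1.01 with 11 at least 2-fold higher, above all random medians. What stays open is whether the siRNAs or the oxygen supply, density or handling of 1 sample may lie behind the higher HIF targets, which cannot be told apart with 1 array per group.

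Replication and ribosome biogenesis genes were lower. After loess the higher of both list medians was -1.03, so a trend with signal does not account for it. Second lists had medians of -0.74 (22 replication genes) and -0.93 (19 ribosome biogenesis genes), both below all random medians, which argues against the choice of genes. Slower growth of the cells of this sample for reasons other than the siRNAs may also give this pattern and cannot be told apart from an effect of the siRNAs with 1 array per group.

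KDM3A was nearly level on the deposited scale while KDM3B was lower by 2.61 or more on the log2 scale. With the arrays level on the hybridization controls KDM3A stood at -0.84 and KDM3B at -3.22, and since 1 factor for all genes leaves the gap as it was by construction, this tests only the level of KDM3A, where a scale difference and a modest depletion cannot be told apart. Whether the KDM3A probe set may be insensitive to the depletion cannot be told apart from a weak depletion, because only 1 KDM3A probe set was measured. KDM3A is itself a known HIF target, so an induction that offset the siRNA stays open as well and was not tested.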

How the results depend on the processing

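No paired analysis was possible because each group held 1 array, and for the same reason no replicate could be left out. The count of genes at least 2-fold higher (1119) became 732 with a pseudocount of the median signal, 3174 with no filter, 270 on the scale of the hybridization controls, and 2723 and 287 at 1.5-fold and 3-fold. The count of genes at least 2-fold lower (1072) became 2504 with no filter, 3483 on the scale of the hybridization controls, and 2452 and 284 at 1.5-fold and 3-fold. On the hybridization-control scale KDM3A moved to -0.84, KDM3B to -3.22 and the median of Wnt/beta-catenin targets to -0.54, by construction of the shift. Epithelial and H3K9 methylation genes lay outside the random range after loess and quantile normalization only. Without the brightest 10% of genes the Wnt median was 0.53 over 11 members, at the 97.485th percentile and inside the random range. The other 44 values of these main results stayed within 1.5 times the count or within the spread. KDM3A and KDM3B have only _x_at and _s_at probe sets and gave no value without them. Among the other lists, 237 values moved by less than the random-list SD, 44 by more, and 2 medians outside the random range turned sign, the mitosis median to 0.089 without _x_at and _s_at probe sets and the interferon median to -0.081 on the scale of the hybridization controls. Of the 44 larger moves of lists, 22 were on the scale of the hybridization controls. Medians inside the random range also turned sign, in 23 values of 13 lists, 10 of them on the scale of the hybridization controls. The replication, ribosome biogenesis, HIF and immediate early medians stayed outside the random range under all 9 alternatives that could move a percentile, the other 2 being shifts of all genes by 1 amount. Among other named genes, 817 values moved by less than the probe-set SD, 121 by more. Of these 121, 90 were on the scale of the hybridization controls, by construction of the shift, and 21 with the pseudocount. Of the other named genes changed 2-fold, LSS turned sign, to 0.0027 with the mean of its probe sets, and of the rest JMJD1C (-0.25), CSF1R (-0.04) and PECAM1 (-0.17) did on the scale of the hybridization controls. The cause of the turned signs was not tested, apart from the constructed shift. Where a signal lies under 50.4 the fold depends on the floor, as the pseudocount shows for OLFML2A, whose log2 ratio went from 5.91 to 2.92. The scaling on the hybridization controls and the filter on the brightest genes were chosen after seeing the data.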

Other observations

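The lists here were written after the results above had been seen, and genes in them are named after their values were seen. Each of their medians lay outside the random range, and the percentiles describe these arrays and test nothing. Glycolytic enzymes outside the HIF list had all 12 measured ratios above 0 by the brightest probe set of each gene. Dimmer probe sets of TPI1 (down to -1.09), PKM (-0.30) and PFKL (-0.11) lay below 0. The list had a median of 0.70 at the 99.2nd percentile of matched random lists, and 2 of the 12 were at least 2-fold higher, ENO2 (2.73-fold) and GPI (2.44-fold). On the scale of the hybridization controls that median would be 0.09. Within the second HIF list ERO1A was 4.45-fold and MXI1 3.68-fold higher, while GYS1 stood at -0.79, and EGLN1 at -0.09 by its brightest probe set with its 3 probe sets reaching up to 1.64. Feedback genes of the MAPK pathway had a median of 0.53 at the 98.2nd percentile, with DUSP4 3.84-fold (its 3 probe sets between 0.95 and 1.94 on the log2 scale), DUSP5 2.51-fold and SPRY2 2.06-fold higher among 12, and on the scale of the hybridization controls that median would be -0.08.

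In 3 other lists the median lay below the random range, while most members changed less than 2-fold. Cytosolic aminoacyl-tRNA synthetases had a median of -0.45 at the 0.11th percentile, with 13 of 17 below 0 and 3 at least 2-fold lower, namely WARS1 and both subunits of the phenylalanyl enzyme, FARSB (2.41-fold) and FARSA (2.32-fold). WARS1 was already known from the largest falls when this list was written. Nuclear pore genes had a median of -0.51 at the 0.82nd percentile, with 14 of 16 below 0 but 1 of 16, NUP88 (3.89-fold), at least 2-fold lower, against 8.53% of all measured genes. Genes of the Fanconi and homologous recombination pathways had a median of -0.67 at the 1.10th percentile, with 3 of 11 at least 2-fold lower and none at least 2-fold higher. In the second replication list CLSPN was 4.18-fold (its 3 probe sets between -2.06 and -0.64) and FEN1 3.81-fold lower, and in the second ribosome biogenesis list RRS1 was 4.18-fold and UTP20 3.34-fold lower.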
